A study of Arabidopsis thaliana with 8 samples.

How the data were processed

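ampDAP-seq windows were analysed for 7 tagged ALOG proteins (LSH1, LSH2, LSH3, G1, LOS1, LOS2 and TMF), each mixed with genomic DNA of 2-week-old Arabidopsis seedlings; the proteins were made by in vitro transcription and translation, per the labels. An input sample was not analysed here. Per the series' design text, 3 replicates were made and only peaks found in every replicate were kept, so each protein has 1 consensus list. Bowtie2, SAMtools and MACS2 are named in the submitters' processing notes, without versions. Parameters, peak thresholds and the genome build are not given in the sources used here. The deposited lists, per the files' contents, give a chromosome, a start and an end for each window; they carry no score, summit, p-value or read count, and every window is 200 bp wide. The authors' depth per library is therefore unknown, and how deeply a list was called can change its length and all overlaps that depend on it. No window lay on organelle DNA. Groups came from the sample titles; the species of origin of each protein is background knowledge. Without separate replicates, tests describe these lists and not the variation between experiments.

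Gene positions came from a RefSeq gene table of assembly TAIR10.1, used for names and for which genes lie at or near a window; all 185 genes of the fixed lists matched. Because the build of the windows is not named, alignment of the coordinates was tested from the data. The share of windows in protein-coding genes was 71.1% without a shift and 67.4% after shifts of 1000 bp either way. For LSH1 windows in 25 segments of 5 Mb, the shift giving the highest share had a median of 0 bp, with a range of -200 to 150 bp. The other lists were not scanned by segment. Only coordinates of windows, counted from 1, are printed. The table has no strand and no exons, so windows were placed only as in a gene body or in a flank.

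Overlap between lists was counted with a minimum of 1 bp and compared with 1000 random placements of the other list on the same chromosomes, with widths kept. Local placement moved each window by 5 to 20 kb. Overlapping windows of all lists were merged into regions. Similarity was the Jaccard index in base pairs, tested by exact two-sided permutation over all assignments of the proteins. Regions of the LSH and not the LOS proteins were set against all 210 assignments. Position relative to 27444 protein-coding genes used window centres and 100 placements. Gene lists (9 lists, fixed before the data were examined) were compared with 10000 random lists matched on gene length in 10 bins, with Benjamini-Hochberg adjustment over lists, or over lists and proteins. Shares have 95% Wilson intervals. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and were tested on simulated lists with planted overlaps, planted similarity and planted gene lists; of simulated gene lists without a change, 3% were called at an unadjusted p under 0.05.

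The genes named were chosen by a rule set before the data were examined: LFY, UFO, AP1, AP3, PI, AG, SEP3, BOP1, BOP2, CUC1, CUC2, CUC3, STM and LSH1 to LSH10; the 4 genes per list with windows of the most proteins; 10 genes with windows of all 7 proteins; and 5 genes for each direction of the LSH and LOS comparison. The rule ranked the last groups, and ties, by peak score. As the lists hold no score, the number of regions was used for the last groups, a choice made after the files were seen, and ties were broken by gene identifier. A gene that the rule selects from the auxin list is not reported here.

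The plan also held analyses that need genome sequence, namely motif enrichment, ranking of short sequences, flanking base preference, motif pairs and motifs by peak strength; these were not run because no genome sequence was used here. Planned positions in promoters, untranslated regions, coding sequence and introns were replaced by gene body and distance to the nearest gene end, and the planned interval of 2000 bp upstream to the gene end by the gene with 2000 bp on both sides. Neighbouring genes can therefore share a window. Alternatives covered the overlap required, the placement, equal list sizes, leaving out each protein, the similarity measure, the gene interval and the matching of random genes.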

Results

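ALOG proteins are plant transcription factors named after Arabidopsis LSH1 and rice G1. The series examined which DNA these proteins bind with ampDAP-seq, in which a tagged protein made in vitro is mixed with fragmented and amplified genomic DNA and the DNA it retains is sequenced. Amplified DNA carries no methylation or chromatin, so the windows describe what the protein can bind in bare Arabidopsis DNA. The DNA came from 2-week-old seedlings. The 8 samples comprised an input, not analysed here, and 1 list of bound windows for each of 7 proteins. As background knowledge, LSH1, LSH2 and LSH3 are Arabidopsis proteins, G1 is from rice, TMF from tomato, and LOS1 and LOS2 from the liverwort Marchantia.

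The lists held 116684 windows of 200 bp on chromosomes 1 to 5. LOS2 had the most windows, 29555, covering 4.96% of the chromosomes, and G1 the fewest, 6902, covering 1.16%. Between them lay LSH2 with 21486 windows, LSH3 with 17263, LOS1 with 14053, LSH1 with 13758 and TMF with 13667. Each list holds the consensus of 3 replicates, so no spread between replicates could be measured and the read depth is unknown. The 95% Wilson intervals given below cover counting error only.

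The windows of the 7 proteins overlapped more than chance placement in every pair of lists, to very different extents. LOS1 windows overlapped a LOS2 window in 92.8% of cases (95% interval 92.4 to 93.3%), TMF windows overlapped LSH2 in 89.2% (88.6 to 89.7%), and LSH3 windows overlapped LSH2 in 84.9% (84.3 to 85.4%). G1 windows were found in the LSH1 list in 78.7% of cases (77.7 to 79.7%), against 71.3% (70.2 to 72.4%) in the longer LSH2 list and 59.0% (57.8 to 60.1%) in LOS2, the longest list. The lowest shares were those of longer lists in shorter ones, with 13.9% (13.5 to 14.3%) of LOS2 windows, 23.2% (22.7 to 23.8%) of LSH2 windows and 27.1% (26.5 to 27.8%) of LSH3 windows in G1, and 24.5% (24.0 to 25.0%) of LOS2 windows in LSH1. With randomly placed windows, the overlap of G1 with LSH1 was 4.51%. In each of the 42 ordered pairs of lists the observed share exceeded all 1000 random placements, and its median ratio to the placed share was 12.1. Overlapping windows were also closely centred, with a median offset between centres of 5 to 15 bp over the 21 pairs, and 60.1 to 90.3% lay within 20 bp, against 10.3% for evenly spread offsets. List length limits these shares, since no more than 6902 windows of any list can have their own partner in G1.

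**Figure D1:**
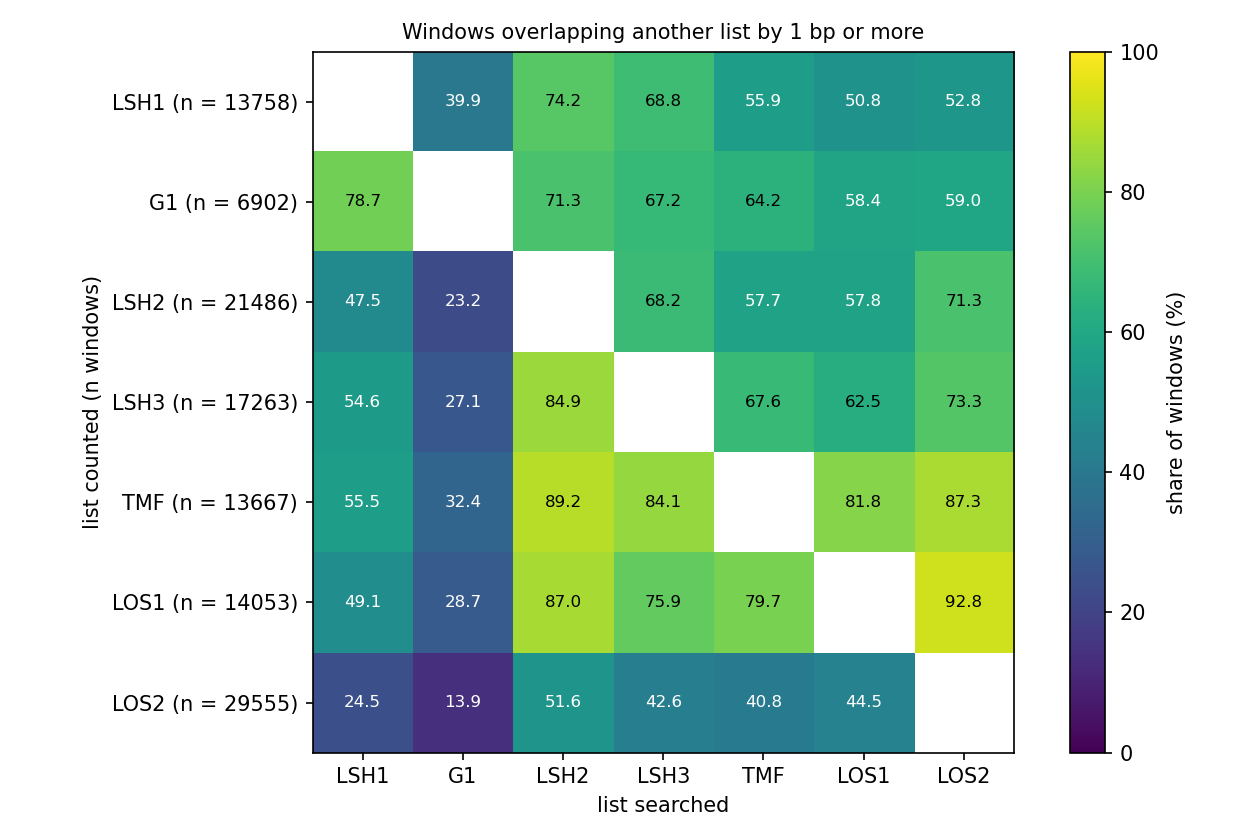
Share of the windows of each list (rows, with the number of windows) that overlap a window of another list (columns) by 1 bp or more, in percent. LOS1 in LOS2 is the highest share at 92.8% and LOS2 in G1 the lowest at 13.9%.

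Merging overlapping windows gave 39850 regions, of which 23756 (59.6%) were present in 2 or more lists and 16094 (40.4%) in 1 list only. The regions present in all 7 lists numbered 3126, against a mean of 0.019 and a maximum of 1 in 1000 random placements. The maximum was 2 when windows were moved by only 5 to 20 kb. Such placements cannot tell binding from background common to all libraries, and the input was not analysed here. A region called bound by a protein is therefore a region held in its list. LOS2 had 11277 regions found in no other list, 38.7% of its own, whereas LOS1 had 105 (0.752%) and TMF 80 (0.589%). LSH1 had 1984 regions of its own, LSH2 1323, G1 736 and LSH3 589. After the regions of LOS2 alone and those shared by all, the most frequent combinations were all lists but G1 and LSH1, with 2881 regions, and all lists but G1, with 2775. Of the regions of G1, the shortest list, 45.7% were bound by all 7 proteins, and leaving G1 out raised the number of regions common to the remaining 6 to 5896. Leaving out any other protein gave 3168 to 3351.

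**Figure D2:**
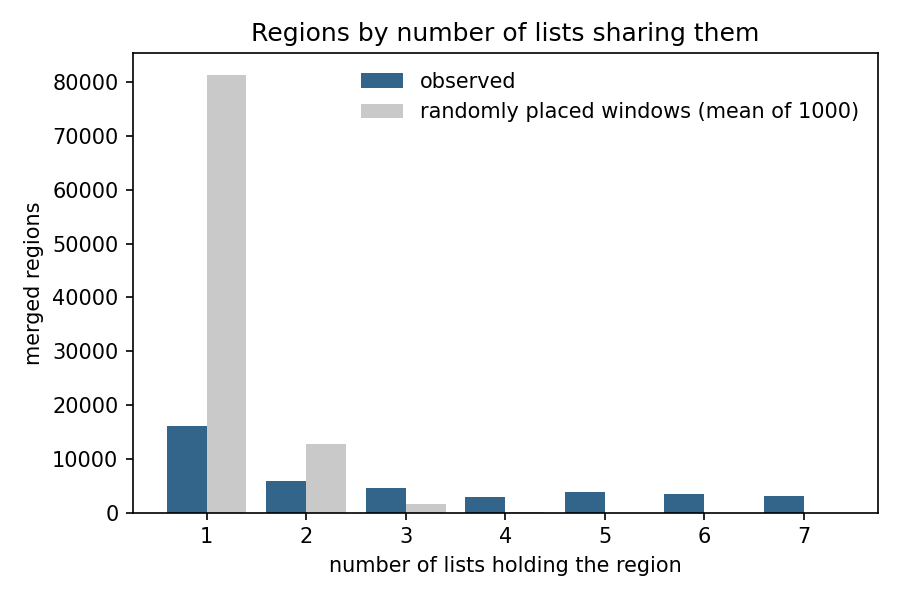
Number of merged regions held by 1 to 7 lists (blue) and the mean number from 1000 random placements of the same windows (grey). The 3126 regions in all 7 lists have a random mean of 0.019.

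No greater similarity among proteins of the same plant was detected. By the Jaccard index, the shared base pairs over the base pairs covered by either list, the most similar pair was LOS1 and TMF at 0.626, a liverwort and a tomato protein. LSH2 and LSH3 followed at 0.551 and LSH3 and TMF at 0.537, and G1 and LOS2 were the least similar at 0.105. This order changed with lists drawn to equal size, a setting chosen after the data were seen. Each draw kept 6902 windows per list at random, which by construction lowers the overlap most for the longest lists. The order in these draws therefore partly follows list length. LOS1 and TMF stayed the most similar pair at 0.237, but LSH1 and G1 came next at 0.220, LSH2 and LSH3 had 0.147, and LSH1 and LOS2 were the least similar at 0.0572. The mean index was 0.435 among LSH1, LSH2 and LSH3 and 0.338 among all other pairs (exact two-sided permutation p = 0.314 over 35 assignments, smallest possible p 0.0286). This difference of 0.0965 was 0.0367 by the share of the smaller list (exact two-sided permutation p = 0.714). In draws of equal size it was 0.0018 (exact two-sided permutation p = 0.971). For LOS1 and LOS2 the index was 0.389, against 0.350 for the other pairs (exact two-sided permutation p = 0.714 over 21 assignments, smallest possible p 0.0476). The result for LOS1 and LOS2 depended on the measure. By the share of the smaller list that overlaps, they were more alike than the other pairs (0.928 against 0.718, exact two-sided permutation p = 0.0952). With lists drawn to equal size the difference was -0.025 (exact two-sided permutation p = 0.571). That sign cannot be read as lower similarity, because the draws drop most windows of LOS2, the longest list.

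Some regions were held by the LSH and not the LOS proteins, and others by the LOS and not the LSH proteins. All of LSH1, LSH2 and LSH3 but neither LOS1 nor LOS2 bound 1850 regions, while LOS1 and LOS2 but none of the LSH proteins bound 913. Of the 1850, 1261 were in no other list, and of the 913, 665. Most of these regions therefore set the LSH or the LOS proteins apart from G1 and TMF as well. With other pairs of G1, TMF, LOS1 and LOS2 required absent, the LSH count was 1555 (G1 and LOS2) to 1737 (G1 and LOS1). Among all 210 ways of assigning the 7 proteins to such sets, 13 gave at least 1850 regions (exact one-sided permutation p = 0.0619, median 140.5, highest 4928) and 50 gave at least 913 (exact one-sided permutation p = 0.238, median 249.5, highest 3764). Neither count therefore passed 0.05. The assignments treat lists of very different length alike, so these p-values partly follow list length. The highest count, 4928, came from requiring LSH1 and G1, the shortest list, to be absent. The order of the counts turned in random draws of equal size, where the LSH regions numbered 319.9 on average and the LOS regions 589.4. These draws also drop windows of the lists that must be absent. A region can then count as lacking a protein whose full list holds it. The turn can therefore not be read as a result about the proteins. Gene by gene, 591 protein-coding genes had windows of all 3 LSH proteins and of neither LOS protein in the gene or within 2000 bp of it, and 288 genes had the reverse.

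Several genes carried repeated regions of this kind. CID10 (AT3G49390) held 3 regions bound by LSH1, LSH2 and LSH3 alone in its gene body, on chromosome 3 at 18315710 to 18315927, 18315932 to 18316136 and 18316366 to 18316654. AT1G19880 held 3 LSH regions without LOS windows in its gene body, the one at 6902828 to 6903066 also with G1. A region of all 7 proteins lay at the edge of its flank, on chromosome 1 at 6906031 to 6906274, with no LOS window centre within 2000 bp. ATB' DELTA (AT3G26030), a regulatory subunit of protein phosphatase 2A, had 3 LSH regions without LOS windows within its gene or flanks, all of which also held TMF or G1. The neighbours AT3G22580 and PHP (AT3G22590) share the same 3 LSH regions, 1 of them in the body of AT3G22580. In the other direction, PROT1 (AT2G39890), a proline transporter, had 3 regions of LOS1 and LOS2 within 2000 bp, and 2 of those also held TMF. ACX1 (AT4G16760), an acyl-CoA oxidase, had 2 LOS regions in its gene body, on chromosome 4 at 9426355 to 9426573 and 9427712 to 9427923. ATB' GAMMA (AT4G15415), AT5G26600 and AT5G50335 had 2 each, and those of AT5G26600 also held TMF.

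Bound windows lay inside protein-coding genes more often than chance placement in every list. The share was 78.2% for G1 (95% interval 77.2 to 79.1%), 77.5% for LSH1 (76.8 to 78.2%), 75.3% for LSH3 (74.6 to 75.9%), 72.4% for TMF (71.6 to 73.1%), 69.6% for LOS1 (68.8 to 70.3%), 68.3% for LSH2 (67.7 to 69.0%) and 66.2% for LOS2 (65.7 to 66.8%). Random placement put about 54.1% of windows inside genes, and none of 100 placements reached the observed share in any list. When windows were instead moved by 5 to 20 kb, so that they stayed in the same neighbourhood, the excess shrank to a ratio of 1.30 for G1, 1.27 for LSH1 and 1.098 for LOS2.

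The lists differed most around the ends of genes. Just outside genes, within 1000 bp of an end, G1 windows occurred at 0.444 times and LSH1 windows at 0.485 times the locally placed frequency, against 0.782 for LSH2 and 0.828 for LOS2. Inside genes within 600 bp of an end, LSH1 held 27.3% of its windows (26.6 to 28.1%), a ratio of 1.11 to local placement, and G1 held 25.8% (24.8 to 26.8%), a ratio of 1.06. The other lists were below local placement there, from a ratio of 0.767 for LOS2 to 0.847 for TMF. Deeper inside genes every list was above it, from 1.32 for LSH2 to 1.48 for LSH3. Gene starts and stops were not separated, because strand was not used here.

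**Figure D3:**
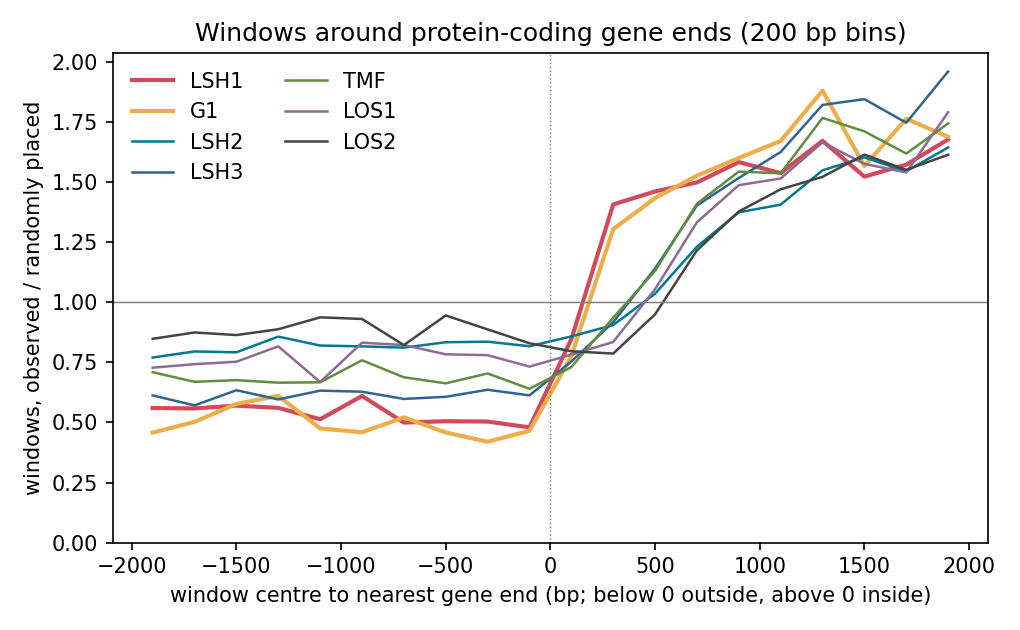
Windows of each list by the distance of their centre to the nearest end of a protein-coding gene, in 200 bp bins, divided by the mean of randomly placed windows (y axis, 1 marks equality). Negative distances lie outside and positive distances inside genes; LSH1 and G1 (thick lines) rise closest to the gene end.

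Windows near genes were common. Between 8987 protein-coding genes (32.7%) for G1 and 21287 (77.6%) for LOS2, of 27444, had a window in the gene or within 2000 bp, and 6202 genes (22.6%) had windows of all 7 proteins. Of the floral meristem and organ identity genes, 8 of 29 had windows of every protein, among them LFY, AP1, CAL and AP3, against a mean of 7.73 in random lists matched on gene length. Flowering time genes, which include GI, TOE1, SNZ and SPL9, reached 10 of 31 (random mean 8.80), and organ boundary and KNOX/BELL genes, such as KNAT6, LOF1, JLO and PNF, 6 of 21 (5.31). The counts were 3 of 14 for meristem maintenance and polarity genes (ATHB8, AS2 and KAN1; random mean 4.44), 5 of 23 for cytokinin genes, with ARR9, ARR15, CKX4 and LOG4 among them (5.42), 2 of 18 for auxin genes, with YUC2 among them (5.03) and 5 of 21 for light signalling genes, including PHYB, CRY1, FHY3 and SPA1 (6.10). The ALOG family itself had 1 of 10, LSH7 (random mean 1.75), and the housekeeping comparison list, with UBQ10, EIF4A1, CDKA1 and RBCS1A, 6 of 18 (4.35). No list stood above random lists of matched genes (one-sided permutation p against the random lists, Benjamini-Hochberg adjusted, 0.979 for all 9 lists). Among the 63 comparisons of a list with a single protein, the lowest adjusted permutation p for more bound genes was 0.864. The lowest unadjusted permutation p was 0.0545, for the housekeeping comparison list and LSH1 (14 of 18 against a random mean of 10.2). For fewer bound genes the lowest adjusted p over the 9 lists was 0.745. By protein the lowest unadjusted p for fewer genes was 0.0385, for auxin genes and G1 (3 of 18 against a random mean of 6.96), with an adjusted permutation p of 0.993. In simulated lists in which genes were 2-fold more likely to be bound by all 7 proteins, 24.5 to 93.5% were called at an unadjusted p under 0.05, depending on the list. With genes 1.5-fold more likely to be bound, 8.5 to 46% were called. The adjusted p used for the lists is stricter, so the share detected by it would be no higher and was not simulated.

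**Figure D4:**
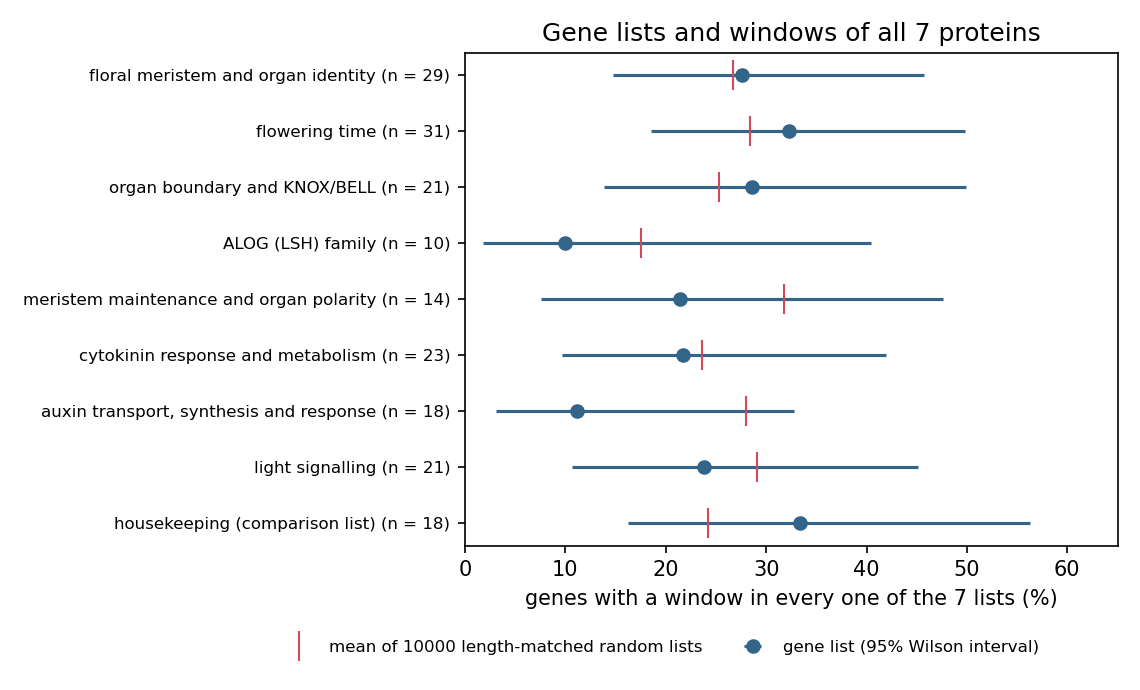
Percent of the genes of each fixed list (n genes) with a window of every one of the 7 proteins in the gene or within 2000 bp (points, with 95% Wilson intervals), beside the mean of 10000 random gene lists matched on length (red marks). The random mean lies within the interval of every list.

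Among genes of flower development, LFY (AT5G61850), a master regulator of floral meristem identity, had 2 regions bound by all 7 proteins, on chromosome 5 at 24844996 to 24845227 in the gene body and at 24842280 to 24842493 in its flank. AP1 (AT1G69120) had 1 in the gene body on chromosome 1 at 25983595 to 25983806, and AP3 (AT3G54340), a petal and stamen identity gene, 1 in the gene body on chromosome 3 at 20120123 to 20120339. CAL (AT1G26310), a paralog of AP1, held 2 in its gene body. UFO (AT1G30950), a partner of LFY in the regulation of AP3, was bound by all proteins but G1 in its gene body, on chromosome 1 at 11036147 to 11036375. AG (AT4G18960), which specifies stamens and carpels, had windows of LSH2, LSH3, LOS1, LOS2 and TMF in its flank only. SEP3 (AT1G24260) had windows of 3 proteins and PI (AT5G20240) of LOS2 alone. SEP2 and SEU had windows of all 7.

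Organ boundary genes varied as much. BOP1 (AT3G57130) had a single region, in its flank on chromosome 3 at 21150601 to 21150808, bound by LSH1, LSH2, LSH3, LOS1 and TMF, while its paralog BOP2 (AT2G41370) had no window of any protein. CUC1 (AT3G15170) had windows of 5 proteins, and CUC2 (AT5G53950) and CUC3 (AT1G76420) of 4 each. STM (AT1G62360), a KNOX gene that maintains the shoot meristem, had windows of 5 proteins and 1 gene body region of LSH1, LSH2 and LSH3 alone, on chromosome 1 at 23060162 to 23060363. Of the ALOG genes, LSH3, LSH4 and LSH6 had windows of every protein but G1, LSH1 and LSH2 of 5, LSH10 of 4, LSH9 of 3, LSH8 of 1 and LSH5 of none. LSH7 (AT1G78815) had a region of all 7 proteins in its flank, on chromosome 1 at 29631455 to 29631847.

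Ranked by the number of regions shared by all 7 proteins, the leading genes were MOM, LNO1, EMB2753, YAK1, ATR, ABCA9, AT1G61390 and AT5G08520, with 4 regions each, and WAKL2 and BES1, with 3 each, taken from ties by gene identifier. MOM (AT1G08060) maintains transcriptional silencing, ATR (AT5G40820) is a DNA damage checkpoint kinase, and BES1 (AT1G19350) is a transcription factor of brassinosteroid signalling. In MOM, LNO1, EMB2753, YAK1 and ATR all 4 lay in the gene body, and in ATR 1 of them was on chromosome 5 at 16348170 to 16348639. Longer genes have more room for windows, and this ranking was not corrected for length.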

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

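Tests under random draws of equal size, local placement that keeps windows inside or outside genes, log2 similarity, other gene intervals and length bins, any overlap with a gene and all genes of the table, and local placement by 5 to 20 kb for the share inside genes, were chosen after the data were seen. The median ratio of observed to placed overlap rose to 23.3 when a reciprocal overlap of 50% was required, which by construction lowers the placed share, and stayed within 1.5 times its value under the other 3 settings. The regions shared by all 7 lists became 13.6 in random draws of equal size, which by construction thin every list, and 5896 without G1. In equal draws the regions of the LSH proteins alone fell to 319.9 and those of the LOS proteins alone to 589.4, which turned their order. The same thinning acts on these counts, more on regions that need 3 lists than on those that need 2. It also drops windows of the lists that must be absent, so regions can count as lacking proteins whose full lists hold them. The turned order can therefore not be read as a result about the proteins. For LOS1 and LOS2 the direction of the similarity difference turned in equal draws (exact permutation p = 0.571) and on the log2 scale (exact permutation p = 0.667). Both settings lower by construction the highest value that a pair with LOS2, the longest list, can reach. Neither turn can therefore be read as lower similarity. By the share of the smaller list, a planned measure, the difference was larger in the original direction (0.211, exact permutation p = 0.0952). No measure passed 0.05; the cause was not tested.

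The ratio of the share inside genes over placement stayed above 1 in every list and setting run. Local placement gave 1.30 for G1, 1.27 for LSH1, 1.22 for LSH3, 1.199 for TMF, 1.15 for LOS1, 1.13 for LSH2 and 1.098 for LOS2. Any overlap of the window with a gene gave 1.38 for G1, 1.37 for LSH1, 1.34 for LSH3, 1.29 for TMF, 1.25 for LOS1, 1.23 for LSH2 and 1.196 for LOS2. All genes of the table gave 1.33 for G1, 1.31 for LSH1, 1.26 for LSH3, 1.22 for TMF, 1.17 for LOS1, 1.15 for LSH2 and 1.12 for LOS2; the cause was not tested. No gene list passed the adjusted threshold under any of the 5 alternatives run for it.

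Not run, for want of a score, were the stronger part of each list and the strongest windows up to the size of the smallest list. Not run, for want of sequence, strand or exons, were all motif alternatives, other promoter lengths and upstream intervals. Windows of 200 bp around centres are the windows as given, centres within 100 bp equal the 50% overlap, and no organelle windows or wider windows were there to leave out. No paired analysis was possible because each protein has 1 list and no replicate numbers. Unknown read depth limits every comparison of list lengths.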

Other observations

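Tests chosen only after the result was seen were those on nested lists, on batch labels, on the comparison of LSH1 with TMF, on base composition, on the gene-dense bins of LSH1, LSH3, G1 and TMF taken apart, and on LOS2-only regions near gene ends, as were the gene families and the positions of regions by list.

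Regions bound by LSH1 alone were concentrated near the ends of genes. Of these 1984 regions, 84.9% lay inside protein-coding genes (95% Wilson interval 83.3 to 86.4%) and 45.8% lay inside a gene within 600 bp of an end, 1.85 times local placement (SD over placements 0.0674). The 540 regions of G1 and LSH1 alone showed 37.6% there (ratio 1.53) and the 736 regions of G1 alone 30.7% (ratio 1.27). Regions bound by all 7 proteins had 20.4% there (ratio 0.839), and the 2881 regions bound by every protein but G1 and LSH1 17.7% (ratio 0.733). Regions of LSH2 alone were inside genes in 56.7% of cases, below local placement (ratio 0.939).

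No gene family stood out among the regions bound by all 7 proteins inside gene bodies. Of 90 families defined by shared symbol roots, none passed a Benjamini-Hochberg adjusted p of 0.05 in either direction. The lowest p for too few genes belonged to CYP genes, which include the cytochrome P450 genes, with 6 of 229 bound against a mean of 15.7 in length-matched random lists (unadjusted one-sided permutation p = 0.0031, adjusted p = 0.279). For too many genes it belonged to RAD genes, with 5 of 15 against 2.07 (unadjusted one-sided permutation p = 0.0414, adjusted p = 1).

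G1 and LSH1 shared more windows than their list lengths would lead to. If all lists were shorter or longer parts of a common ranking, G1 would lie in LSH2 at least as often as in LSH1, but its share in LSH1 was 7.40 percentage points higher. The share of the regions of G1 and LSH1 alone inside genes was 1.40 times local placement (SD 0.0434), which argues against background spread evenly over the local sequence. Background that itself favours genes is not excluded, since base composition is untested. Regions of all 7 proteins had a lower ratio, 1.21. A more similar DNA preference of the proteins is a candidate explanation that stays open: among 1376 G1 regions that LSH2, LSH3, LOS1 and LOS2 lack, 45.3% were in LSH1 and 7.27% in TMF, a difference of 38.1 points, but in the same part of the genome 23.3% of the 2679 LSH1 regions and 39.8% of the 251 TMF regions were in G1, a comparison added after the difference was seen that runs the other way. A shared preparation batch cannot be told apart from it, as 0 samples carry a batch label.

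The excess of windows inside genes may in part reflect fewer usable reads in repeat-rich, gene-poor DNA. In the gene-dense bins of 100 kb the share inside genes stayed above random placement in every list. The ratio was 1.106 for LOS1 (SD 0.00838) and 1.089 for LSH2 (SD 0.00594). In LSH1, LSH3, G1 and TMF the lowest ratio was 1.15 (TMF, SD 0.00908). These 4 lists were set apart after the ratios were seen, so their passing the bound is no separate test. The rule set beforehand covered all 7 lists, and there the lowest ratio was 1.07 (LOS2, SD 0.00546), between its bounds. Fewer usable reads therefore cannot be told apart from a preference of the proteins. Base composition stays untested, as 0 windows had a sequence here.

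The many regions of LOS2 alone may be background, weaker sites from a deeper list or sites of LOS2 itself. Their share inside genes was 1.06 times local placement (SD 0.00779), between the bounds set beforehand. They were depleted inside genes near gene ends (ratio 0.731, SD 0.0133), much like the LOS2 regions shared with another list (ratio 0.795), which argues against background spread evenly over the local sequence. Background that itself avoids gene ends is not excluded. These LOS2-only regions lay 200 to 1000 bp from a window of another list 1.11 times as often as locally placed windows (SD 0.0142). That is above the bound set beforehand for deeper calling, but by less than the SD. As depth is unknown too, deeper calling cannot be told apart from binding by LOS2 alone.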
